A study of Caenorhabditis elegans with 2 samples.

How the data were processed

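Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole, mixed-sex larvae of the nematode Caenorhabditis elegans in the first larval stage (L1), collected 6 hours after synchronization as starved L1 larvae. Per the labels, the worms stably carried a transgene encoding the forkhead transcription factor FKH-8 with a GFP-FLAG tag at its C terminus in an unc-119 mutant background, and chromatin was sheared by microtip sonication. The labels disagree on the antibody: the description names one against GFP and the antibody field names fkh-8. The description was followed here. The design had 1 group with 2 biological replicates and no other condition, so no difference between groups was tested. A control sample is mentioned in the labels and in the deposited file lists but was not used here.

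The deposited data were 8 peak lists in narrowPeak format, 4 on the ce10 and 4 on the ce11 genome build, per the labels: 1 list for each replicate, 1 list from both replicates pooled, and 1 list of peaks that passed a threshold on the irreproducible discovery rate (IDR), which scores how well peak ranks repeat between replicates. Per the deposited file lists, each replicate's list came from that replicate's alignments and a control file, and the pooled list from the alignments of both replicates. The first 3 kinds of list include background regions as input for IDR, per the labels. The aligner, the peak caller and the IDR cutoff were not given in the sources used here. Each deposited peak carries a signal value whose scaling is not stated. It also carries the −log10 of a q-value, as deposited in the format's ninth column, and the summit's offset from the peak start. The deposited −log10 q-values shared an upper limit within each list, which 82.5% of the reproducible peaks had reached, so the peaks were ranked by signal. Signal values were used only to rank and describe peaks within a list. The files hold no read counts, so the sequencing depth of each replicate is unknown, and the intervals given below cover the counting of peaks or genes only. The reproducible list on ce11 was exactly the 4963 pooled peaks with the highest signal.

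Coordinates are 1-based and on ce11 throughout. Gene models came from Ensembl release 115 on the matching assembly, and sequence came from the RefSeq genome. The ends of all ce11 peaks lay within the reference chromosomes. A gene was called bound when the summit of a reproducible peak lay in its promoter window, from 1000 bp upstream to 200 bp downstream of the 5′ end of a nuclear protein-coding gene (19973 genes). Annotated 5′ ends in this species are often trans-splice sites. To give values per replicate, the 4963 peaks with the highest signal in each replicate's list (its best peaks) were treated the same way, and means ± SD are over these 2 values. Agreement of the replicates was the share of best peaks overlapping by 1 base or more. Random expectation came from 1000 circular shifts of all summits along each chromosome, two-sided, for which 0.002 is the smallest p possible. Peaks per chromosome were compared with chromosome length by an exact binomial test. Lists of genes were tested with Fisher's exact test, two-sided, against all other coding genes, with Benjamini-Hochberg adjustment over 25 lists. All genes sharing a symbol prefix with 15 or more members were tested in the same way over 116 prefixes. For 8 sequence consensuses, a match on either strand within 100 bp of the summit was compared with a window of the same width 500 bp to one side, the side drawn at random, by an exact McNemar test with Benjamini-Hochberg adjustment. The same ratio was computed for up to 100 shuffled column orders of each consensus as a control for base composition. Confidence intervals are exact Clopper-Pearson 95% intervals, and intervals of correlations and ratios came from 1000 bootstrap draws over peaks. Peaks and genes are not independent replicates.

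Gene lists, consensuses, tests, thresholds and the rule for named genes were fixed before the data were examined. The lists were the components of the cilium (the union of intraflagellar transport particle, transport motors, BBSome, transition zone and other ciliary genes, and each alone), sensory signalling, pan-neuronal genes, neuronal transcription factors, muscle, intestine, epidermis, germline, glia, translation factors, chaperones, ribosomal proteins, histones, collagens, neuropeptides, chemoreceptors, nuclear receptors, ceh homeobox genes, forkhead genes and bHLH genes. The cilium union left out unc-119, dnc-1 and odr-4, which stayed in the list of other ciliary genes. Some list members overlap, since the cilium lists are nested. The rule named fkh-8, unc-119 and daf-19 whatever their values. It also named up to 25 bound cilium genes and up to 3 bound genes of each other list by signal, up to 5 unbound cilium genes in alphabetical order, the genes at the 10 highest peaks, and the 2 members with the highest signal in each prefix family past the threshold. The text gives only some of these. Alternatives were a stricter and a looser peak set, each replicate's best peaks alone, other windows, the nearest gene, another gene background, a logistic model with upstream distance and gene length, circular shifts, other overlap rules, other motif windows and the ce10 lists.

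The list test and the motif test were tested on simulated data. A list bound at a raised rate was called in 19 of 20 draws over 19973 genes, and of 50 random lists per draw 0 were called in all draws. An X-box planted at 2.86% of 4963 random positions raised the share with a match by 2.90 percentage points (exact p = 9.31e-19), and with nothing planted p was 1. Random positions did not carry the difference in GC content between real summits and flanks, so this simulation does not cover its effect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.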

Results

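Binding of GFP-tagged FKH-8 was mapped by ChIP-seq in whole L1 larvae of C. elegans in 2 biological replicates. FKH-8 is a forkhead transcription factor known as a regulator of ciliary genes in sensory neurons, which are the ciliated cells of this worm. The question the design addresses is where in the genome the tagged protein is recovered. The peak lists on ce11 held 19354 peaks for replicate 1, 21452 for replicate 2, 17956 for the pooled replicates and 4963 in the reproducible set that passed the IDR threshold. The reproducible peaks had deposited signal values from 94.9 to 2102, with a median of 164. Most of them (85.8%) were 416 bp wide, so a summit rather than a width locates each peak. The read depth behind the lists is unknown.

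The highest peaks repeated closely between the replicates. Of the 4963 best peaks of replicate 1, 4149 (83.6%, 95% interval 82.5 to 84.6%) overlapped a best peak of replicate 2, against a mean of 3.72% and a maximum of 4.57% in circular shifts (permutation p = 0.002, the smallest possible). In the other direction the share was 84.8%. Overlap fell toward the cutoff: of replicate 1's best peaks split by signal into 5 equal parts, it was 992 of 992 in the highest part, 94.0% in the middle part and 51.0% in the lowest. Peaks of the lowest part lie next to the cutoff, where small changes of rank remove a peak from the other list. With equally many best peaks from each replicate, the share was 84% for 100, 85.8% for 500 and 87.8% for 1000. Those peaks have the highest signals, so these shares do not describe low signal. With more peaks from each replicate, the share was 86.01% for 2481, 83.6% for 4963 and 76.55% for 9926. The share thus became lower as peaks of lower signal entered. Whether the fall toward the cutoff reflects changes of rank there or poorer repeatability at low signal cannot be told from these values. For the 4960 reproducible peaks present in both whole lists, signal correlated across peaks with a Spearman coefficient of 0.843 (95% interval 0.832 to 0.853) and a Pearson coefficient of 0.894 on log10 values. Each peak took the signal of the highest peak overlapping it in each replicate's list, so some neighbouring peaks carry the same values. These coefficients are across peaks, which are not independent.

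**Figure D1:**
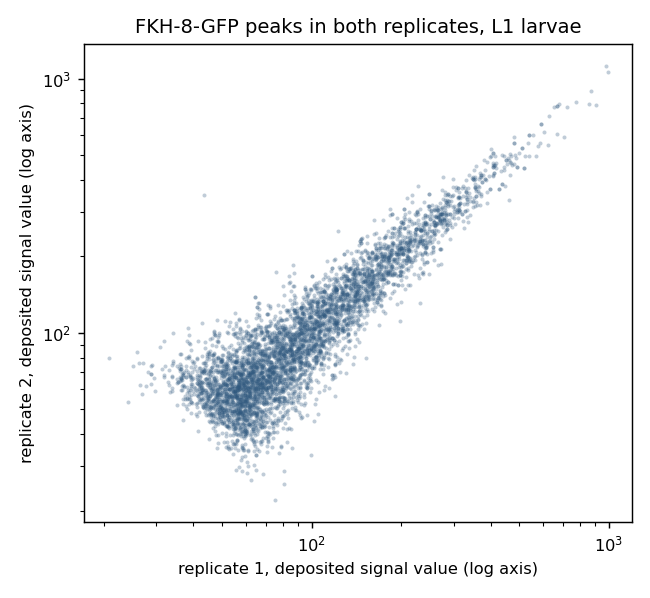
Deposited signal value of each reproducible peak in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), 1 point per peak for the 4960 peaks found in both lists. Each takes the value of the highest peak overlapping it in that replicate's list, so some neighbouring peaks share values. The points follow a single diagonal that widens at low signal, with a Spearman coefficient of 0.843.

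Reproducible peaks lay mainly between coding genes, and near 5′ ends more often than shifted peaks. Intergenic here means outside protein-coding genes, so a summit in a non-coding gene can count as intergenic. Summits were intergenic in 68.5% of peaks, against 37.1% in shifted peaks, and in coding sequence in 2.26%, against 24.5% (permutation p = 0.002 for each). Introns held 24.5%, below the 33.4% of shifted peaks (permutation p = 0.002), and exons outside coding sequence held 4.82% against 4.94% (p = 0.731). Promoter windows held 44.5% of summits, against 21.2% in shifted peaks (permutation p = 0.002). The best peaks of the replicates gave 44.2% ± 0.598 (SD, n = 2). The share in promoter windows was 56.5% in the highest of 5 parts by signal and 39.1% in the lowest. Peaks outside these windows were a median of 2538 bp from the nearest coding 5′ end. By exact binomial tests against chromosome length, chromosomes III (1.15 times, adjusted p = 4.25e-05) and X (1.15 times, adjusted p = 5.13e-06) had more peaks, and IV (0.869 times, adjusted p = 3.10e-05) and V (0.834 times, adjusted p = 6.33e-09) fewer. Chromosomes I and II did not differ from their share of length (exact adjusted p = 0.228 and 0.477). With 9926 pooled peaks the excess on III was no longer past the threshold (1.04 times, exact adjusted p = 0.179), and with the 2481 highest peaks chromosome I also had more (1.17 times, adjusted p = 0.000987).

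In all, 2752 of 19973 coding genes (13.8%) were bound. Of 25 gene lists, 9 were bound more often than other genes, 4 less often and 12 neither. Components of the cilium were bound at 33 of 62 genes (53.2%, 95% interval 40.1 to 66.0%), against 13.7% of other genes (odds ratio 7.20, Fisher's exact test, adjusted p = 1.40e-12). Best peaks bound 35 of them in replicate 1 and 29 in replicate 2. All 33 peaks were present in both replicates' whole lists, as were 4960 of all 4963 reproducible peaks, so this does not set cilium peaks apart. The odds ratio was 6.20 in the logistic model with upstream distance and gene length (n = 19973 genes, adjusted p = 1.43e-11).

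Of the separate cilium lists, the intraflagellar transport particle, which carries cargo along the axoneme, was bound at 14 of 20 genes (exact adjusted p = 7.37e-08). The highest signal in that group was at osm-5 (X:2984263 to 2991478), with a peak at X:2984092 to 2984294, an intergenic summit 67 bp upstream of the gene and a signal of 446.7, rank 433 of 4963. Next came ift-43, with a signal of 414.1 and a summit 437 bp upstream that lay in coding sequence and also in the window of mdt-26, and dyf-11, with 410.7 and an intergenic summit 184 bp upstream. Peaks also lay at ifta-1 (signal 367.6), dyf-2 (262.4), ift-20 (233.7), daf-10 (175.8), ift-81 (175.0), dyf-3 (173.0), che-2 (162.4), osm-6 (153.6) and ift-74 (140.2). The BBSome, a membrane trafficking complex of the cilium, was bound at 5 of 8 genes (exact adjusted p = 0.00482), among them bbs-8 (signal 189.3), bbs-4 (172.6) and bbs-5 (139.3). Its call was lost with the best peaks of replicate 2 alone, which bound 3 (exact adjusted p = 0.152), and with the 2481 highest peaks, which bound 2 (0.206). The list of other ciliary genes, which holds the 3 genes left out of the union, was bound at 8 of 16 (exact adjusted p = 0.00163), including nekl-4 (277.1), tub-1 (229.4), hyls-1 (219.3) and arl-13 (195.5). Transition zone genes, at 5 of 14 (exact adjusted p = 0.0602), and transport motors, at 3 of 7 (adjusted p = 0.0991), did not pass the threshold. These 2 calls depend on the rule for binding: transition zone genes passed in 6 alternatives, such as the nearest gene (7 of 14, exact adjusted p = 0.0125), and motors in 4, such as windows from 2000 bp upstream to 500 bp downstream (6 of 7, exact adjusted p = 0.000711). Both counts include circular shifts, which coding genes as a whole also exceeded. Best peaks of replicates 1 and 2 bound 6 and 4 transition zone genes, and 3 and 2 motors. The peaks of the 3 bound motors ranked 2672 to 4056, so none was among the 2481 highest. The highest of all cilium peaks was at tmem-107 of the transition zone (signal 670.3, rank 131), with a summit 51 bp upstream that also lay in the window of the ribosomal protein gene rps-26. Among the motors, klp-11, dylt-2 and xbx-1 were bound. No reproducible peak lay in the windows of arl-3, arl-6, bbs-2, bbs-9 or ccep-290. Of the 33 summits, 25 were intergenic, 8 lay within a coding gene and 8 fell in the window of another coding gene as well. The median rank was 2304, so most cilium peaks were not among the highest.

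**Figure D2:**
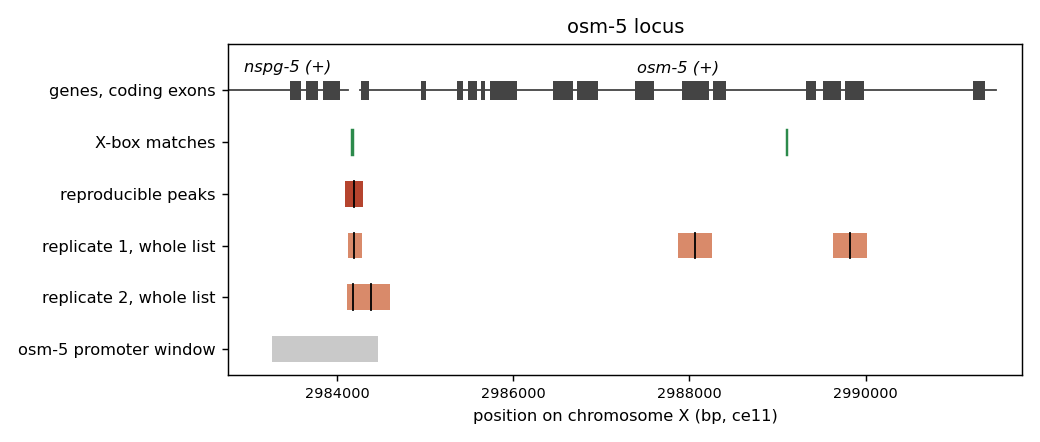
Map of osm-5 and its surroundings on chromosome X (x axis, position in bp on ce11), with genes and coding exons, X-box matches, the reproducible peak, the peaks in each replicate's whole list (black lines mark summits) and the promoter window. The reproducible summit, at 2984196, lies 26 bp from the centre of an X-box match and 67 bp upstream of the gene, and both replicates have a peak there.

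Genes of protein synthesis were often bound. Cytosolic ribosomal proteins were bound at 67 of 78 genes (85.9%, 95% interval 76.2 to 92.7%, odds ratio 39.0, exact adjusted p = 4.27e-45), with 67 in each replicate, and translation factors at 23 of 31 (adjusted p = 3.14e-13). By the nearest gene the ribosomal share fell to 38 of 78 (48.7%, odds ratio 4.35, exact adjusted p = 3.82e-09). The ribosomal protein genes included rpl-3 (signal 2060, rank 2, summit 279 bp upstream), rpl-15 (1662, rank 5) and rpl-20 (1579, rank 6); the translation factor iff-2 had a signal of 1142 (rank 18). Chaperone and stress genes were bound at 13 of 30 (exact adjusted p = 0.000236; by the nearest gene 10 of 30, odds ratio 2.27, no longer past the threshold, adjusted p = 0.0724), with hsp-1, a constitutive Hsp70, at 1495 (rank 7) and hsp-60 at 954.9. Pan-neuronal genes were bound at 14 of 32 (exact adjusted p = 0.000125), among them unc-108 (769.5), egl-21 (558.9) and maco-1 (473.2). Nuclear receptors were bound at 50 of 269 (18.6%, exact adjusted p = 0.0493). Against genes with a gene-class symbol only, that difference was not past the threshold (odds ratio 1.11, exact adjusted p = 0.579).

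Chemoreceptors, the serpentine receptors that sense odours, were bound at 87 of 1308 genes (6.65%, exact adjusted p = 7.42e-16), collagens at 5 of 156 (3.21%, adjusted p = 7.70e-05), neuropeptides at 10 of 140 (7.14%, adjusted p = 0.0398) and epidermal genes at 0 of 34 (upper limit of the interval 10.3%, adjusted p = 0.0249), each less often than other genes. The reading depends on the reference. Coding genes as a whole exceeded circular shifts, with 2752 bound against a mean of 1114. The 87 chemoreceptors exceeded their own shift mean of 65.9 by a smaller factor (permutation, adjusted p = 0.0385), so their lower share was not reversed. Against shifts, collagens, neuropeptides and epidermal genes did not pass the threshold (permutation, adjusted p = 0.422, 0.804 and 0.444). Neuropeptides turned to higher shares with 9926 pooled peaks (34 of 140, odds ratio 1.19, exact adjusted p = 0.508) and by the nearest gene (35 of 140, odds ratio 1.52, adjusted p = 0.0532), and were no longer past the threshold with the best peaks of replicate 1 alone (11 of 140, exact adjusted p = 0.102). The epidermal call was lost by the nearest gene (2 of 34, exact adjusted p = 0.0912). With 9926 pooled peaks the difference for chemoreceptors was no longer past the threshold (odds ratio 0.894, exact adjusted p = 0.194). Markers of other tissues did not pass the threshold: muscle at 2 of 32 (exact adjusted p = 0.382), intestine at 1 of 33 (0.121), germline at 2 of 40 (0.214) and glia at 0 of 17 (0.214). Neither did sensory signalling genes, at 8 of 42 (exact adjusted p = 0.435), with eat-16 (signal 773.9), gcy-33 (227.8) and tax-6 (208.8) bound, histones at 10 of 72 (adjusted p = 1), ceh homeobox genes at 4 of 63 (0.145), forkhead genes at 1 of 15 (0.771), which was daf-16, and bHLH genes at 4 of 25 (0.801). Sensory signalling did pass by the nearest gene (17 of 42, odds ratio 3.10, exact adjusted p = 0.00181) and in windows from 2000 bp upstream to 500 bp downstream (odds ratio 2.17, adjusted p = 0.0394). It also exceeded circular shifts (3.44 times their mean, permutation, adjusted p = 0.00909). Coding genes as a whole exceeded shifts too, so this does not set the list apart from other genes. Neuronal transcription factors were bound at 4 of 40 (odds ratio 0.695, exact adjusted p = 0.736), but by the nearest gene the direction turned and the list passed (13 of 40, odds ratio 2.19, exact adjusted p = 0.0366). One of these was daf-19, which encodes the RFX factor known to act through X-boxes in ciliary genes, with a signal of 579.3, rank 208, and a summit 82 bp upstream of its 5′ end.

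**Figure D3:**
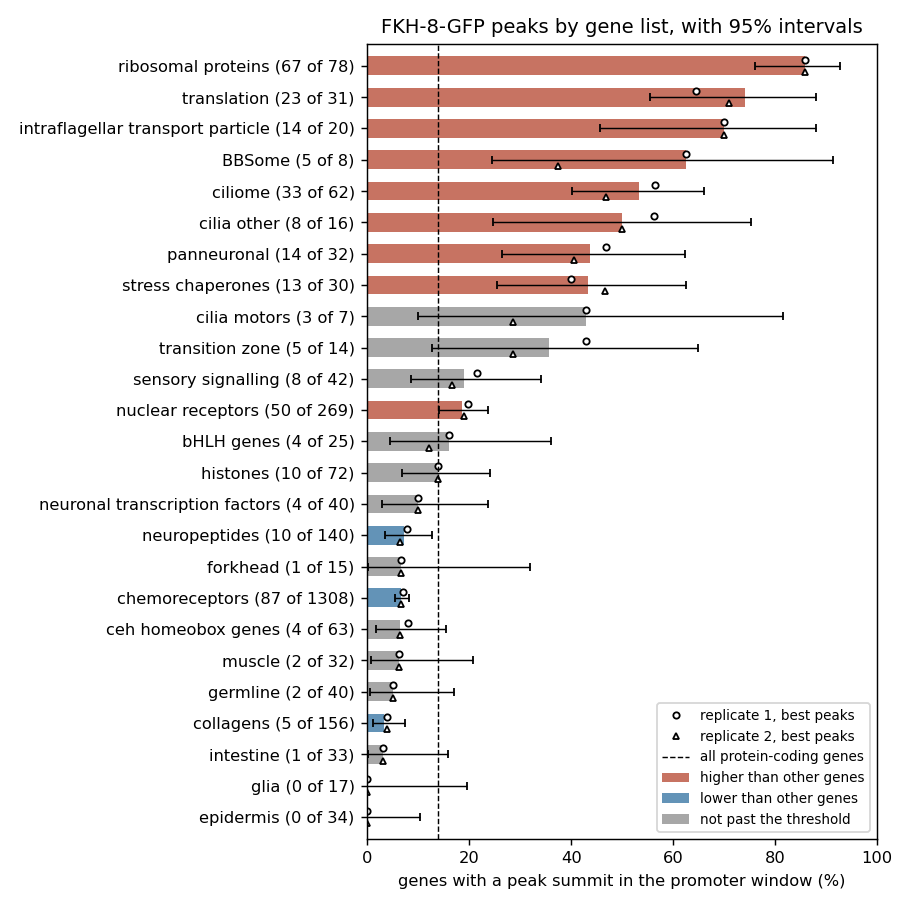
Percent of the genes in each of 25 lists with a reproducible peak summit in the promoter window (x axis), with exact 95% intervals as lines, the 2 replicates' best peaks as open symbols and all coding genes (13.8%) as a dashed line. Ribosomal proteins are at 85.9%, the cilium list (ciliome) at 53.2% and epidermal genes at 0.

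Across 116 symbol families, 15 were bound more often than other genes and 15 less often. Families with higher shares were ribosomal (rpl, 38 of 47; rps, 29 of 31), translation initiation (eif, 9 of 16), J-domain chaperones (dnj, 13 of 29), ubiquitin-conjugating enzymes (ubc, 10 of 21), secretion and membrane traffic (sec, 9 of 19; rab, 9 of 20; vps, 11 of 31), nuclear pore (npp, 10 of 26), vacuolar ATPase (vha, 8 of 20), mitochondrial ribosome (mrpl, 13 of 41), cytochrome oxidase (cox, 6 of 15), taf (7 of 17), and the phenotype-named lin (18 of 47) and daf (10 of 26). C-type lectins (clec, 4 of 240), F-box genes (fbxa, 6 of 170; fbxb, 3.85%), collagens, oac (0 of 56), twk potassium channels (0 of 44), nas (0 of 37) and several chemoreceptor families (str, 8 of 193; srh, 12 of 220; srt, 0 of 61) were among those with lower shares. The lin family included lin-54 (signal 1342, rank 11), whose summit also lay in the window of rpl-12, and lin-35 (762.0), which shares its summit with vps-51.

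Sequence at the summits held X-boxes and GACGC more often than the flanks, and the forkhead consensus RYAAAYA less often, though more often than most of its shuffled orders. An X-box, the RFX site RYYNYYWTRRNRAC, lay within 100 bp of 3.49% of summits and in 1.85% of flanking windows (ratio 1.88, exact McNemar test, adjusted p = 5.87e-07), a ratio above 99 of 100 shuffled orders. GACGC, an alternative core described for FOXN-type forkhead factors, was found at 30.7% of summits and 11.4% of flanks (ratio 2.69, exact adjusted p = 1.18e-124), above all 29 shuffled orders, the highest of which had 2.64, within the 95% interval of 2.45 to 2.93. It rose with signal, from 22.8% in the lowest of 5 parts of the peaks to 43.7% in the highest, while GC content rose from 39.1 to 45.3% and the comparison motif GAGAGA from 26.3 to 46.6%. RYAAAYA was found at 31.3% of summits and 34.2% of flanks (ratio 0.916, exact adjusted p = 0.00242), a ratio above 95 of 100 shuffled orders (median 0.770), so its lower share at summits is not read as depletion of the site. With flanks at 1000 bp the ratio was 1 (exact adjusted p = 1), and within 200 bp of the summit it was 1.01 (adjusted p = 0.699). Of the comparison motifs, GAGAGA (34.6% against 10.0%, ratio 3.45, exact adjusted p = 3.89e-189), GGGCGG (8.62% against 3.08%, adjusted p = 4.76e-33) and the E-box CANNTG (62.2% against 52.7%, adjusted p = 1.70e-21) were more frequent at summits, and the GATA site (adjusted p = 9.22e-09) and TAATTA (adjusted p = 0.000463) less frequent. GC content was 41.4% within 100 bp of the summit and 34.9% at 500 bp, so ratios of GC-rich and AT-rich consensuses are to be read beside their shuffled orders: GGGCGG was above only 20% of its 5, while the GATA site, at 0.851, was above 39% of 100 (median 0.891) and TAATTA, at 0.796, above 92.3% of 13 (median 0.637). The lower share of these 2 at summits is not read as depletion either. The E-box, at 1.18, was above 96% of its 100 shuffled orders, and GAGAGA, at 3.45, above 94.7% of its 19 (highest 3.72). Lying above most shuffled orders was therefore not particular to the forkhead consensus. Of the 33 bound cilium genes, 19 had an X-box within 100 bp of the summit, 12 RYAAAYA and 7 GACGC. At osm-5 the match was GTTACTATGGCAAC at X:2984163 to 2984176, and at che-2 it was GTTGTCATGGTGAC at X:481321 to 481334, 8 bp from the summit.

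**Figure D4:**
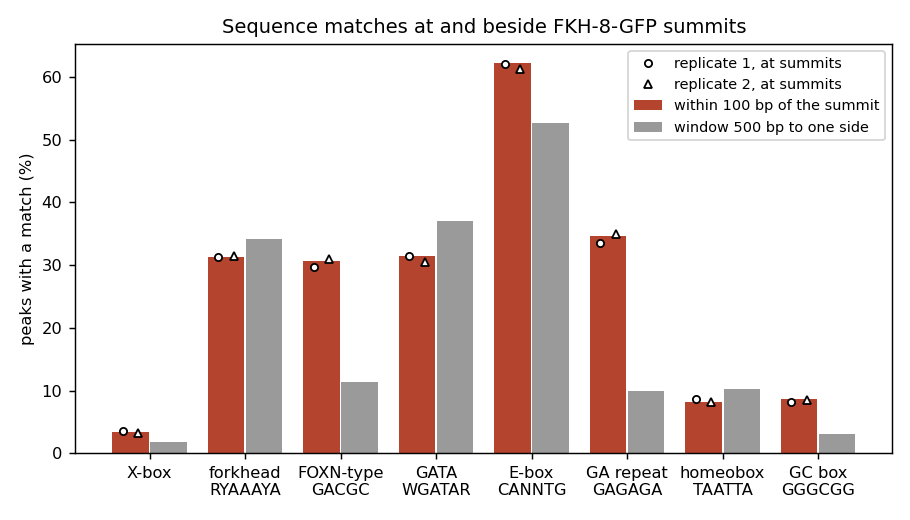
Percent of the 4963 reproducible peaks with a match to each consensus (y axis) within 100 bp of the summit (red bars) and in a window 500 bp to one side (grey bars); open symbols give each replicate's best peaks at summits. GACGC is at 30.7% against 11.4% and RYAAAYA at 31.3% against 34.2%.

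Of the 100 highest peaks, 64 lay in a promoter window and 11 in that of a ribosomal protein gene. The highest (signal 2102, III:10759081 to 10759466) had an intergenic summit 46 bp upstream of tasp-1 that also lay in the window of K01G5.10. The third (1763, V:1151295 to 1151720) lay in no promoter window but within the lincRNA gene linc-128, and its nearest coding gene was cmd-1, which encodes calmodulin, 4780 bp away. The fourth (1681) was 157 bp upstream of cdc-48.1, an AAA ATPase gene, and ranks 8 to 10 were at nhl-2 with tag-340 (1492), tos-1 (1438) and Y39E4B.6 (1428). The fkh-8 gene itself (II, starting at 6189623) had no peak within 2 kb in the reproducible, pooled or replicate lists on ce11. It lies in a stretch of 105 kb without a pooled peak, although replicate 1 has a peak in it at 6175068 (signal 63.25, rank 3471 of 19354). Whether part of this stretch was masked or corrected for the transgene is not given in the sources used here, so the absence of peaks there, also at mks-2, is not evidence of no binding. At unc-119 (III), whose mutation is in the strain background, the highest peak had a summit at 10903465 within the gene and a signal of 761.6 (rank 90), and no reproducible summit lay in its promoter window. The transgene was taken to carry a rescuing copy of unc-119, so extra copies could raise the signal there. This was not tested. Within 2 kb of daf-19 lay 6 reproducible peaks, against 0.783 from the genome mean.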

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

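The test on lower peaks was chosen after the lists had been seen. Peaks in the pooled list that fell below the reproducible set, used above in the alternatives with 9926 pooled peaks but not for the cilium share of 33 of 62, also lay at cilium genes. In that alternative 41 of the 62 cilium genes were bound, so some of the genes counted below are already in it. Of the 29 cilium genes without a reproducible peak, 14 (48.3%, exact 95% interval 29.5 to 67.5%) had such a peak in the promoter window, against 18.5% of 17192 other genes without one (odds ratio 4.11, two-sided Fisher's exact test, p = 0.000261) and a mean of 4.10 in circular shifts (p = 0.002, the smallest possible). The highest of the 12993 lower peaks at these genes were at dyf-18 (signal 92.5, pooled rank 5118), jbts-14 (89.9), dyf-5 (80.7) and che-11 (79.0), and 9 of the 14 genes had an overlapping peak in both replicates' lists. The remaining 5 had it in 1 list. Both replicates' lists include background regions, and the share for all lower peaks is not given here, so 9 of 14 is not read as support. No explanation was tested.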

How the results depend on the processing

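The test on each list's share of bound genes in circular shifts was chosen after the data had been seen. Cilium binding kept its direction and stayed past the threshold in all 12 alternatives, with odds ratios or ratios to shifts from 3.59 to 9.18, as did the share of summits in promoter windows in 7 (37.6 to 58.2%), the X-box ratio in 7 (1.59 to 2.35) and the GACGC ratio in 7 (1.85 to 3.60). Replicate overlap was 77.8% when each peak had to be covered by 50%, 79.5% with summits within 100 bp, 86.01% with the 2481 best peaks, 76.55% with 2 times as many and 83.7% on ce10. The signal correlation was 0.824 with summits within 100 bp, 0.870 in the 2481 highest peaks, 0.767 over all overlapping peaks and 0.843 on ce10. By the share of bound genes in circular shifts, 7 lists passed in place of 13. With windows from 2000 bp upstream to 500 bp downstream, 49 families passed in place of 30. The forkhead ratio was 1.01 within 200 bp and 1 with flanks at 1000 bp. In 5 cases a list changed direction with at least 1 value past the threshold. Neuropeptides turned to an odds ratio of 1.19 with 2 times as many pooled peaks, 1.52 by the nearest gene and a ratio of 1.23 to shifts. Neuronal transcription factors turned to 2.19 by the nearest gene, and chemoreceptors to 1.32 times the shifts. The ratios to shifts are no turn against other genes, since coding genes as a whole exceeded shifts by more (2752 bound, mean 1114). For the other cases the cause was not tested. Of the other single lists, chromosomes and motifs under each alternative, 296 were counted as unchanged, 23 lost the threshold and 21 passed it. Unchanged means the same direction and side of the threshold, or a turn of direction with neither value past it. Lists that lost it in some alternative were the BBSome, other ciliary genes, chaperones, nuclear receptors, epidermis, collagens, neuropeptides and chemoreceptors. Lists that passed it with higher shares only in some alternatives were transition zone, motors and sensory signalling. Intestine, germline and ceh homeobox genes passed it in some with lower shares. Neuronal transcription factors passed with a higher share by the nearest gene (exact adjusted p = 0.0366). By the nearest gene the odds ratio of ribosomal proteins was 4.35 in place of 39.0. Of 126 named genes, 27 changed between bound and unbound by the nearest gene, 20 with the 2481 highest peaks and 19 in windows of 500 bp either side. Not run were the ce10 alternatives for chromosomes, where no ce10 lengths were used, and for the fkh-8 locus, where no ce10 gene models were used, and the logistic model for epidermis and glia, with 0 bound genes. The replicates share no second group, and read depth, which can affect how many peaks a list holds, is unknown. No paired analysis was possible because there was 1 group.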

Other observations

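The values on non-coding genes, the shuffled orders within 200 bp, the gap around fkh-8 and X-boxes in unbound cilium windows were chosen after the lists had been seen. So were, at ribosomal protein genes, each forkhead-type site alone and either site in the highest part of the peaks. Summits lay within 100 bp of 137 of 612 tRNA genes (22.4%), against a mean of 8.75 in circular shifts, with at least 134 in each replicate. The same held for 66 of 346 snoRNA genes (mean 5.70 in shifts) and 16 of 129 snRNA genes (mean 1.90), each with an adjusted permutation p of 0.0028 over 7 gene types. For miRNA genes the count was 10 of 261 (mean 3.81, permutation, adjusted p = 0.0373), and for lincRNA genes 18 of 194 (mean 12.3, adjusted p = 0.160). Pseudogenes, at 22 of 2128 against 148.1, and piRNA genes, at 18 of 15363 against 148.4, had fewer (permutation, adjusted p = 0.0028 for each).

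No pooled peak lay between 6124834 and 6229801 on chromosome II, an interval of 105 kb with 17 coding genes lying wholly inside it, fkh-8 and the transition zone gene mks-2 among them. Whether part of this region was masked or corrected for the transgene is not given in the sources used here, so the absence of peaks in it is not evidence of no binding. It was the fourth longest of 17950 gaps between neighbouring pooled summits, whose median was 2456 bp. The gap spanned 54.8 kb in replicate 1, the 42nd longest of 19348, and 77.9 kb in replicate 2, the 6th longest of 21446. The 50 kb up to and including the replicate 1 boundary at 6175068 held only that 1 peak, against 9.65 from the genome mean. Replicate 1 had a peak inside the pooled gap at 6175068 (signal 63.25, rank 3471) and replicate 2 had peaks at 6149680 and 6227542, so the interval was not masked as a whole in either replicate's list. For the narrower part around fkh-8 this stays open. The 50 kb before and after the pooled gap held 19 and 8 peaks, against 8.95 from the genome mean.

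X-boxes were found at 20 of 35 reproducible peaks in cilium windows (57.1%), against 67 of 2172 other promoter peaks (3.08%, odds ratio 41.9, two-sided Fisher's exact test, p = 1.74e-20). In the 23 bound cilium windows that hold an X-box, the median distance from summit to X-box was 16 bp. Random positions in the same windows gave a median of 350 bp (one-sided permutation, p = 0.0001, the smallest that 10000 draws give), and positions at the offsets of other promoter peaks gave 215 bp (p = 0.0001). This argues against X-boxes being near by promoter content alone, or by crowding at 5′ ends as at other promoter peaks. Bound cilium summits had a median offset of −63 bp from the 5′ end. Crowding particular to cilium promoters was not simulated, so it stays open. X-boxes were also present in 17 of 29 unbound cilium windows, against 23 of 33 bound ones (Fisher's exact test, p = 0.431). A hypothesis that stays open is that tagged FKH-8 may be recovered at cilium genes together with a factor on the X-box. It was not tested: peaks of the RFX factor in the same stage, or of tagged FKH-8 in worms without that factor, would test it, and neither was analysed here.

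The high peaks at ribosomal protein genes were not carried by 1 library, since 85.9% of these genes were bound in each replicate's best peaks. Of the 64 peaks in their windows, 32 (50%) had RYAAAYA or GACGC within 100 bp, against 57.8% of 2143 other promoter peaks (odds ratio 0.731, two-sided Fisher's exact test, p = 0.248), so an excess of forkhead-type sites was not detected. RYAAAYA alone was less frequent, at 20.3% against 35.9% (exact p = 0.0112), and GACGC alone was not, at 37.5% against 33.7% (odds ratio 1.18, exact p = 0.592). Both single-site tests were chosen afterwards. The 64 peaks had a median rank of 694.5, against 2236 for other promoter peaks. Within the highest of 5 parts by signal, also chosen afterwards, 51.2% of 41 had either site, against 61.3% of 519 (two-sided Fisher's exact test, p = 0.245). RYAAAYA also lay in 34.2% of flanks of all peaks, so having or lacking such a site does not show how a peak arose. Recovery at these promoters without such a site, as at highly transcribed or accessible promoters in general, may contribute and stays open. Peak lists of other tagged proteins, which would bear on it, were not used here, and no biological explanation was tested.

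The forkhead consensus RYAAAYA was not enriched at summits. Imprecise summits cannot be told apart from other explanations. The ratio within 200 bp was 1.01 (95% interval 0.974 to 1.05), under the 1.1 set beforehand, but that bar left out base composition: shuffled orders at that width had a median of 0.914, and over this median the ratio was 1.102 (1.065 to 1.145), against 1.19 (1.12 to 1.26) within 100 bp. Base composition could hide an enrichment. The rule set beforehand asked for a ratio above 95% of the shuffled orders. The ratio of 0.916 met it narrowly, above 95 of 100 orders and their 95th percentile of 0.910. A further condition, that the interval clear this percentile, was not part of that rule. The interval of 0.865 to 0.970 spans the percentile, so this cannot be told apart at this number of peaks. No biological explanation was tested.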
